A study of Homo sapiens with 16 samples.

How the data were processed

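Gene expression was measured in 8 established lung cancer cell lines (A427, A549, H23, H358, H460, H661, H1437 and H1703), each grown on tissue culture plastic (2D) and in Matrigel, a basement membrane extract (3D). Each line gave 1 array per culture, so there were 16 arrays, 8 per culture. Per the labels' protocols, RNA was extracted with phenol and chloroform, and 200 ng of total RNA was labelled with biotin and hybridised to the U133 Plus 2.0 array of Affymetrix. That array measures a transcript with probe sets, groups of short oligonucleotides that lie mostly near its 3' end.

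The deposited values are log2 ratios for 54675 probe sets. From the values themselves, 63.5% of probe sets have a linear median of 1 over the 16 arrays, so their reference was their own median. A median counted as 1 when its log2 lay within 0.001 of 0, here and in the filter below. The other 36.5% have a median under 1, as when a dim probe set is divided by a fixed minimum in place of its median, and none lies above 1. The lowest ratio is 0.01, reached by 297 values, of which 92 lie in genes that were tested. The software, the summary of probes into probe sets and the normalisation between arrays are not given in the sources used here. Because each probe set has a reference of its own, differences between arrays can be read from these ratios and levels of different genes cannot be compared. Medians of the arrays lay between -0.28 and -0.07 and their interquartile ranges between 0.735 and 0.895 (log2). A microarray gives no read depth, so the number of arrays limits the precision.

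Gene names came from the platform's annotation table, with symbols brought up to date through gene identifiers and the RefSeq gene table of the GRCh38.p14 assembly. In that annotation, 41097 probe sets had 1 gene symbol, 1801 had several and 11777 had none. Probe sets with several or none were left out, as were 58 probe sets of Y-linked genes and XIST. No genome build was named for the array values, so no coordinates are given. Of 19741 genes with a probe set, 10511 had more than 1, and the probe set with the highest mean over all 16 arrays represented the gene. The 5967 genes whose representative had a median under its reference were left out as dim, and 13774 genes were tested.

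That filter departs from the one fixed before the data were examined. The earlier rule left out genes under the 40th percentile of mean level and assumed that the values were levels. On ratios it would remove 2922 genes whose median equals its reference and keep 993 dim ones, so it was run as an alternative instead. The rule of the highest mean was kept as written, although the mean of a ratio is no level, and other ways to represent a gene were run beside it.

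Differences between 3D and 2D were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend), with the cell line as a block, over all 16 arrays. Pairing rests on the cell line named in the labels. As a check, the array of the same line in the other culture was the closest array for 16 of 16 arrays, with correlations of 0.780 to 0.924 over tested genes. Replicate numbers follow the order of deposition and pair nothing. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over the 13774 genes. With 1 array per line and culture, the p-values measure the spread of the 3D minus 2D difference over lines, and differences within a single line have no replicate check. Errors are SDs over the 8 lines.

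Before the data were examined, 40 gene lists (pathways, cell states and markers of other cell types) were fixed and tested with limma's fry, using its directional PValue with Benjamini-Hochberg adjustment over the 40 lists. That PValue asks whether the genes of a list move, on balance, one way, and does not compare the list with other genes. For each list, members were also counted after adjustment over the list alone. Camera with a preset correlation of 0.01 and with an estimated correlation were alternatives.

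The rule for named genes, also fixed before the data were examined, takes the 12 highest and 12 lowest fold changes among called genes with the same sign in at least 7 of 8 lines, up to 4 members of each list with the smallest p, and for each line the 3 genes highest and the 3 lowest against the mean of the other 7 lines. The text names all of the first group and a part of the other groups. Other genes named were chosen after their values were seen, and the text marks them. Likeness of the lines was compared as the mean of 1 minus Pearson's r over 28 pairs of lines, with an exact two-sided permutation test over all 256 swaps of 2D and 3D within lines. Array controls were compared with an exact two-sided sign-flip permutation test over the 8 lines, whose smallest possible p is 0.00781.

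The steps were tested on simulated data built on the 13774 genes and the 8 pairs, with 200 changed genes. Of the genes changed 1.5-fold, 62.7% were recovered, of those changed 2-fold 85.1%, and of those changed 3-fold 98.5%, with 6 false calls and 0 calls of the wrong sign. All 3 shifted lists were found at a shift of 0.4 (log2), and 0 others were called. Errors were drawn independently for each gene, whereas the correlation estimated in the data was 0.54 for mitosis and 0.38 for DNA replication. The simulation therefore does not show how fry performs on lists of correlated genes.

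Alternatives fixed before the data were examined were the fit without the line as a block, no filter and a filter at the 60th percentile of the mean ratio, the mean of all probe sets of a gene, leaving out probe sets whose type allows matches to several transcripts (suffix s or x), quantile normalisation, centring on array medians, eBayes without trend and with robust estimation, array weights, leaving out each line, testing every probe set, a 1.5-fold minimum, the set tests above and Spearman's correlation. Those chosen after seeing the data were the 40th percentile filter as first written, the mean of a gene's probe sets that are not dim, and the level of the 18S rRNA probe sets of each array as a covariate. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.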

Results

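The series compared 8 lung cancer cell lines in 2 kinds of culture. In 2D the cells grew on tissue culture plastic, and in 3D they grew on top of a thin layer of Matrigel under medium that held 2% Matrigel. Density and medium were matched between the cultures. There was 1 array per line and culture, so the 8 lines served as 8 pairs, and every value below is a log2 difference of 3D minus 2D unless stated. The main question was which genes differ between the cultures across the lines.

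ARRDC4, an arrestin family gene induced by glucose, rose in 3D by 2.14 ± 1.13 (SD, n = 8 lines; log2), a 4.42-fold difference, and was higher in 8 of 8 lines (limma, adjusted p = 0.0140). TFPI, an inhibitor of the coagulation cascade, rose by 2.09 ± 1.01 and CFAP96, a cilia and flagella protein, by 1.97 ± 0.83, both in 8 of 8 lines. The interferon-inducible membrane protein IFITM1 rose by 1.59 ± 0.87, and SPAG4, known as a hypoxia-inducible gene, by 1.43 ± 0.72. FAM162A, a mitochondrial protein induced by hypoxia, rose by 1.75 ± 1.05 and was higher in 7 lines. SELENOP, a secreted selenium carrier, rose by 1.39 ± 0.97, the long non-coding RNA PCAT6 by 1.29 ± 0.80 and LGALS3BP, a secreted galectin ligand, by 1.28 ± 0.97. The remaining 3 of the 12 highest genes were ANXA1 (1.84 ± 1.49), ETNK1 (1.64 ± 0.77) and DNAJC7 (1.40 ± 0.97), and in each of them the gene's probe sets parted. For ANXA1, the second probe set gave -0.26. For DNAJC7, the other probe sets gave -0.29 and -0.59, and for ETNK1 a second probe set was itself called lower, at -0.51 (adjusted p = 0.0397 over all probe sets).

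Among the genes that fell, GNL3L, a nucleolar GTPase, decreased by 1.97 on the log2 scale (SD 0.71, adjusted p = 0.00597) and was lower in 8 of 8 lines. Its other probe sets gave -2.32, -0.68 and -0.21, the last not called. HEATR3 fell by 1.91 (SD 1.05), with a second probe set at -0.58, and RSBN1L fell by 1.88 (SD 1.04), with its 3 other probe sets between -0.19 and 0.07. DNAL1, a dynein light chain, fell by 1.62, with other probe sets called lower at -1.27 and higher at 0.43. The mRNA export factor ALYREF fell by 1.42 and the kinetochore gene SKA3 by 1.31. On their representative probe sets MCCC2, PPFIBP1, BPNT1, SMG1P5 and BLTP3B fell by 1.30, 1.28, 1.28, 1.27 and 1.22. Other probe sets gave -0.17 and -0.41 for MCCC2, -0.35 for BPNT1, -0.69 to 0.09 for PPFIBP1 and -0.80 to 0.16 for BLTP3B, with 3 of 4 above 0 in the last. VHL, whose product targets hypoxia-inducible factors for degradation, had a value of -1.54 ± 1.15 on its representative probe set and 0.04 on its other one. Of these 12 genes 10 had other probe sets that were not dim, 21 in all, of which 8 were called, 7 of them lower. Averaged within each gene, those others had a median of -0.33 over the 10 genes, against -1.48 for the representatives, which were picked for their low values. Among the 12 highest, 6 genes had 16 such probe sets, of which 8 were called, 7 of them higher, and their median over genes was 0.33, against 1.79 for the representatives. Other probe sets lay between 0.65 and 1.15 for TFPI and between 1.04 and 1.08 for FAM162A, and at 0.86 for CFAP96.

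**Figure D1:**
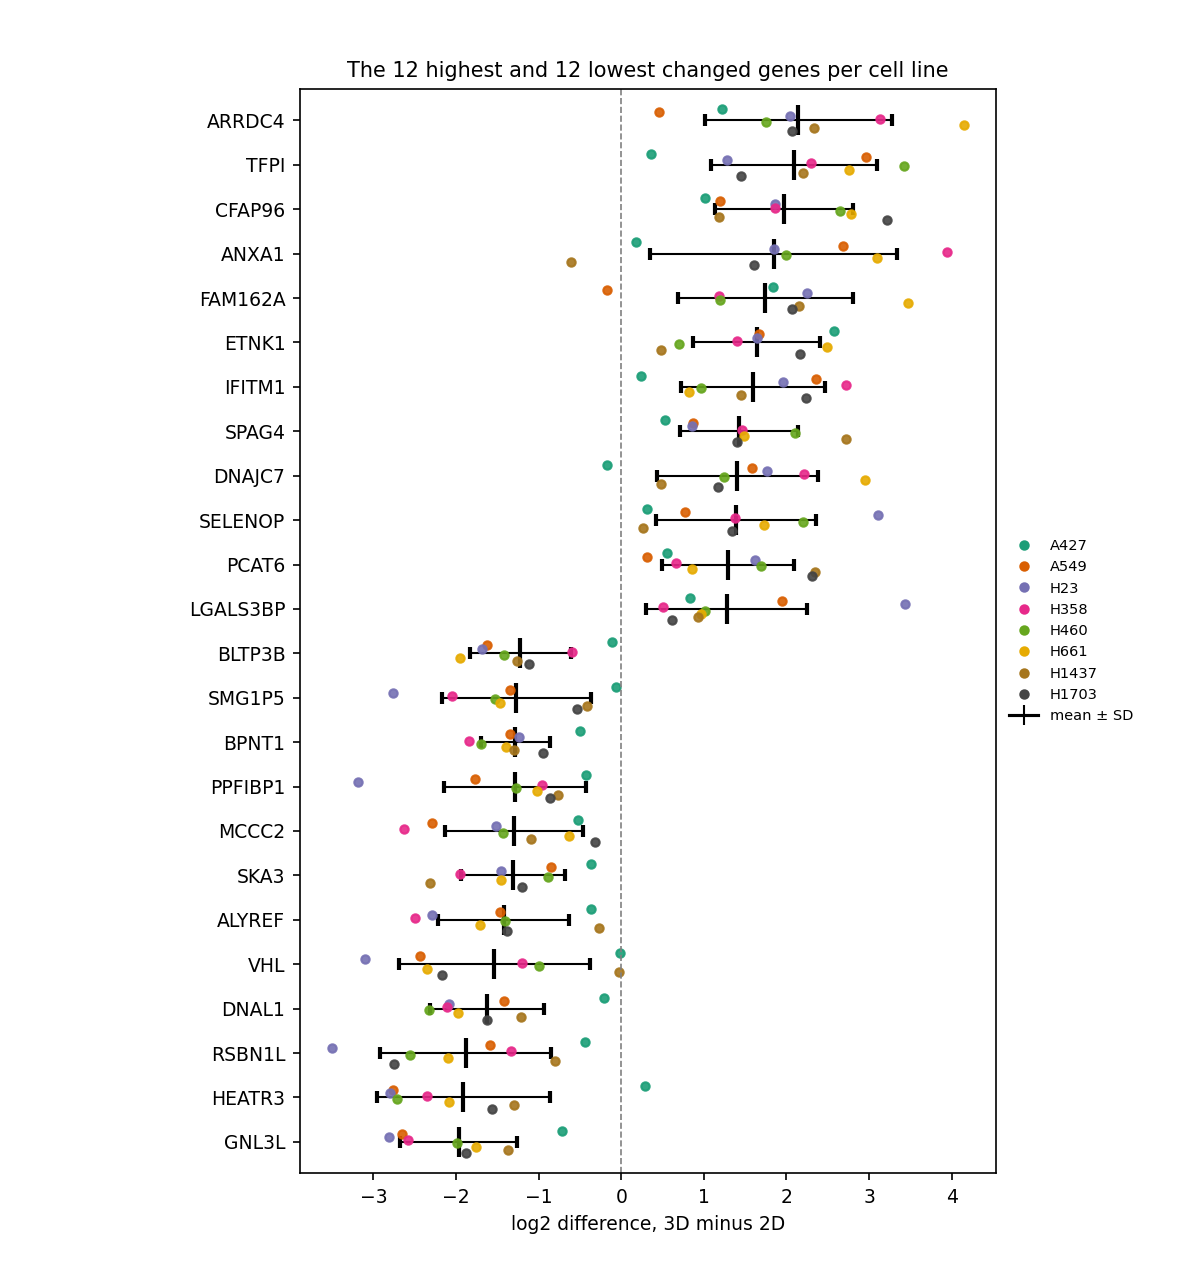
Log2 difference of 3D minus 2D (x axis) for the 12 highest and 12 lowest named genes (y axis), 1 point per cell line and bars for the mean ± SD of 8 lines. ARRDC4 lies above 0 in 8 of 8 lines and GNL3L below 0 in 8 of 8, while A427 often lies nearest to 0.

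Of 13774 tested genes, 854 (6.20%) changed, 319 higher and 535 lower in 3D (limma, Benjamini-Hochberg). Most changes were small, with a median size of 0.55 (log2), and 369 genes reached 1.5-fold, 147 higher and 222 lower. A 2-fold change was reached by 66 genes, 37 higher and 29 lower. Of the 854, 840 had the same sign in at least 7 lines and 581 in all 8. Among all tested genes 7.41% had the same sign in 8 lines, where chance gives 0.781%. The count depends on the lines included. It was 155 without H358, 163 without H1703, 207 without H460, 218 without H23, 289 without H661 and 443 without A549. Without H1437 it was 810 and without A427 923. With the 18S rRNA level of each array as a covariate 0 genes were called by limma (1359 had an unadjusted p under 0.05), and the 854 genes kept their sign. That level was lower in 3D in 8 of 8 lines, least so in H1437 (-0.08) and A427 (-0.13), the lines whose removal kept the count highest. The covariate therefore overlaps with culture and makes the culture difference less precise. A call lost in that fit, here or below, does not show that 18S accounts for the change. Among the named genes that fit moved LGALS3BP to 0.41, SELENOP to 0.40, DNAJC7 to 0.93, HEATR3 to -1.16, RSBN1L to -0.90, ALYREF to -0.84, VHL to -0.60, SMG1P5 to -0.45 and PPFIBP1 to -0.42.

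Genes of the hypoxia response rose together in 3D. Of 22 tested members of this list of 25, 8 rose and 0 fell (13 rose when adjusted over the list alone), and the list mean was 0.57 ± 0.16 (SD, n = 8), higher in 8 of 8 lines (fry, adjusted p = 0.000889; adjusted p = 0.0574 with an estimated correlation). BNIP3L, a mitophagy receptor, rose by 1.23 ± 0.41, the glycolytic regulator PFKFB4 by 1.12 ± 0.53 (0.07 on its other probe set), the disulfide-forming oxidase ERO1A by 0.89 ± 0.44 and the histone demethylase KDM3A by 0.85 ± 0.44, each in 8 of 8 lines. The other 4 members that rose, named after their values were seen, were BNIP3 (1.23 ± 0.97), P4HA1 (1.11 ± 0.72), ANKRD37 (1.03 ± 0.85) and MXI1 (0.81 ± 0.49). With all probe sets averaged, dim ones included, the calls of P4HA1 (0.51) and ANKRD37 (0.42) were lost. The glucose transporter gene SLC2A1 had 1.24 ± 1.48 (0.79 without H661) and NDRG1 1.01 ± 1.03, and neither passed the test over all genes. Glycolysis genes shifted up with a list mean of 0.28 ± 0.15, again in 8 of 8 lines (fry, adjusted p = 0.0116; adjusted p = 0.240 with an estimated correlation). Here 2 of 16 members rose, PFKL (0.53 ± 0.22) and PGK1 (0.68 ± 0.50), while 6 rose and 1 fell when adjusted over the list alone. GPI stood at 0.67 ± 0.58, outside the calls over all genes. The hexokinase gene HK2 was the 1 that fell in the list alone, at -0.57 ± 0.53, but its other probe sets gave -0.33 and 0.86, the last one called higher (adjusted p = 0.0427 over all probe sets). In the same arrays the 18S rRNA probe sets were lower in 3D by a mean of -1.15. With that level as a covariate the hypoxia list mean was 0.60 (adjusted p = 0.0601) and the glycolysis mean 0.14 (adjusted p = 0.219), so both calls ended. Both were also lost with the filter at the 60th percentile, at 0.43 for hypoxia response (adjusted p = 0.0613) and 0.31 for glycolysis (0.296), and the glycolysis call without probe sets of suffix s or x (0.26, adjusted p = 0.182).

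Genes of DNA replication fell in 3D. Of 26 tested members, 15 fell and 0 rose (20 fell when adjusted over the list alone), with a list mean of -0.44 ± 0.24 and lower values in 8 of 8 lines (fry, adjusted p = 0.0116; adjusted p = 0.388 with an estimated correlation). The origin licensing factor CDC6 fell by 0.89 (SD 0.57), MCM10 by 0.64 (SD 0.36), the polymerase epsilon subunit POLE2 by 0.52 (SD 0.28) and POLA1, the catalytic subunit of polymerase alpha, by 0.48 (SD 0.25). Of 24 mitosis genes 10 fell (18 when adjusted over the list alone). Their mean was -0.46 ± 0.33, lower in 7 of 8 lines (fry, adjusted p = 0.0304; adjusted p = 0.562 with an estimated correlation). The mitotic kinase PLK1 fell by 0.83 (SD 0.61), the kinetochore protein CENPF by 0.75 (SD 0.46) and the spindle factor TPX2 by 0.67 (SD 0.40). NUSAP1 fell by 0.58 (SD 0.31), with -0.22 and no call on its other probe set. PLK1 passed in 11 of 20 alternatives, where its smallest fall was -0.51. H661 and H358 had the lowest mitosis means, -0.91 and -0.88, and A427 had 0.09. The 18S rRNA probe sets were lower in the same lines (mean -1.15), and with their level as a covariate the means were -0.44 for replication (adjusted p = 0.201) and -0.36 for mitosis (adjusted p = 0.394). The mitosis call was also lost with the filter at the 60th percentile (-0.36, adjusted p = 0.0692) and on leaving out any single line except A427, with adjusted p from 0.0541 without A549 to 0.0904 without H460, through 0.0619 without H1703, 0.0663 without H661, 0.0694 without H1437, 0.0758 without H23 and 0.0834 without H358.

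**Figure D2:**
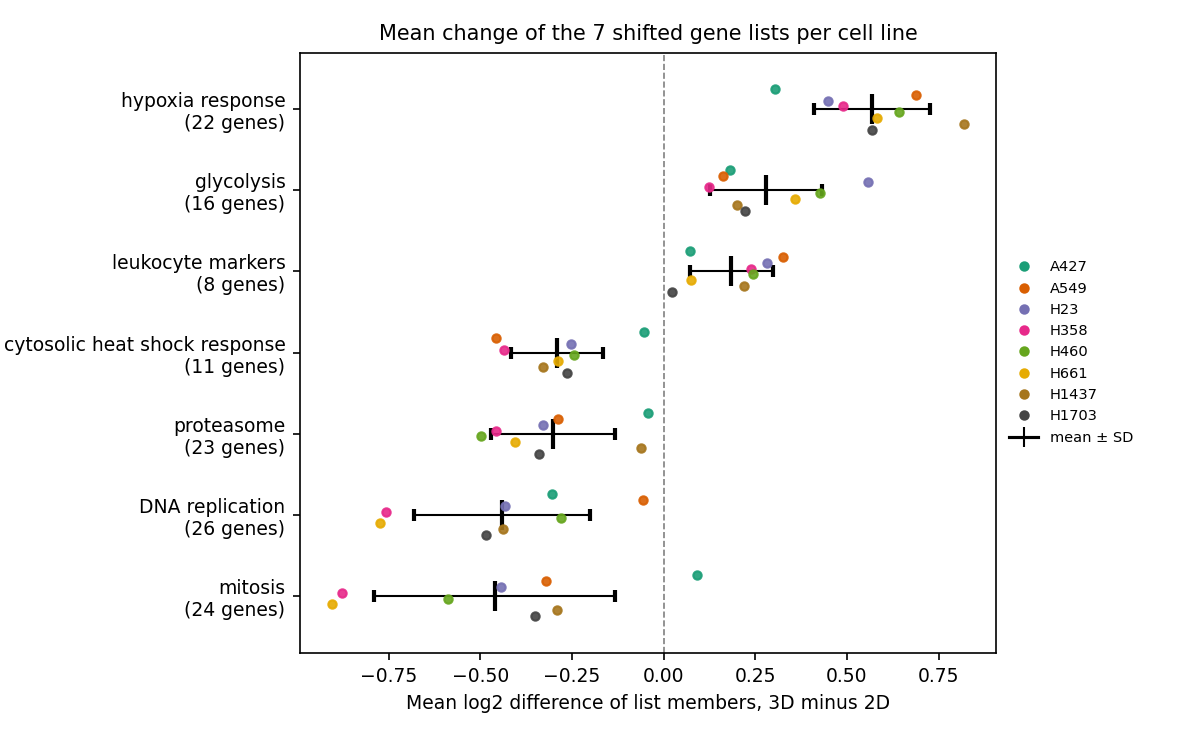
Mean log2 difference of 3D minus 2D (x axis) over the tested members of the 7 lists that passed the list test (y axis), 1 point per cell line and bars for the mean ± SD of 8 lines. Hypoxia response lies between 0.30 in A427 and 0.82 in H1437, and DNA replication below 0 in 8 of 8 lines.

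Proteasome genes fell as well, 9 of 23 members over all genes. Adjusted over the list alone, 18 fell and 1 rose. The list mean was -0.30 ± 0.17, lower in 8 of 8 lines (fry, adjusted p = 0.0116; adjusted p = 0.562 with an estimated correlation). PSMB2, a subunit of the catalytic core, fell by 0.64 (SD 0.30; -0.74 and -0.13 on its other probe sets that were not dim), PSMA7 by 0.50 (SD 0.28), the regulatory ATPase PSMC3 by 0.45 (SD 0.22) and PSMD1 by 0.44 (SD 0.25). The cytosolic heat shock list had a mean of -0.29 ± 0.13, lower in 8 of 8 lines (fry, adjusted p = 0.00328; adjusted p = 0.240 with an estimated correlation), and 2 of 11 tested members fell (7 when adjusted over the list alone). These were the HSP70 exchange factor HSPH1, which fell by 0.82 (SD 0.27; -0.40 and not called without probe sets of suffix s or x), and the collagen chaperone SERPINH1, which fell by 0.44 (SD 0.18). With the 18S level, itself lower by a mean of -1.15, as a covariate, the proteasome mean was -0.21 (adjusted p = 0.260) and the heat shock mean -0.29 (adjusted p = 0.0621).

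In ribosome biogenesis and MYC targets 4 of 24 members fell, UTP20 by 0.99, RRP9 by 0.66, NOLC1 by 0.54 and NME1 by 0.53. UTP20 passed in 13 of 19 alternatives, where its smallest fall was -0.59. The other probe sets of NOLC1 gave -0.39 and -0.11, neither called, and it passed in 8 of 19 alternatives. When adjusted over the list alone 7 fell and 1 rose, and the list mean of -0.26 ± 0.29 did not pass (fry, adjusted p = 0.178). Of 24 oxidative phosphorylation genes UQCRC2 fell by 0.83 and NDUFA5 by 0.50 on their representative probe sets (5 fell when adjusted over the list alone), with a list mean of -0.14 ± 0.13 (adjusted p = 0.178). The other probe sets of UQCRC2 gave 0.15 and 0.07, and without probe sets of suffix s or x NDUFA5 stood at 0.28. Ribosomal protein genes had a mean of 0.08 ± 0.12 with 0 of 20 called (adjusted p = 0.281), which sets them apart in value from the biogenesis list without a test of that difference.

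No list of adhesion, matrix or cell state genes passed the list test. Basement membrane genes, which encode the kind of protein that Matrigel contains, had a mean of 0.21 ± 0.23, higher in 7 of 8 lines. That list had a fry p of 0.0393 before adjustment and 0.178 after it, with 0 of 11 tested members called. LAMA5 stood at 0.43 ± 0.35 and LAMB2 at 0.53 ± 0.57. Focal adhesion and integrin genes had a mean of 0.01 ± 0.28 and a median of -0.02 (adjusted p = 0.954), interstitial matrix 0.10 ± 0.29 (0.575), matrix proteases -0.02 ± 0.50 (0.954) and actin and SRF targets -0.08 ± 0.22 (0.472). For the proteases fry's direction was up although the mean was under 0. Epithelial junction genes had a mean of 0.13 ± 0.28 (0.472), with TJP1 at -0.28 ± 0.29, CLDN3 at 0.42 ± 0.52 and DSP at 0.66 ± 0.84, none of them called. Keratins had a mean of -0.01 ± 0.56, a median of 0.09 and fry's direction up (0.954). In the mesenchymal list, mean -0.08 ± 0.35 (0.681), the transcriptional repressor ZEB1 fell by 0.77 (SD 0.44), lower in 8 of 8 lines. Its call was lost when all probe sets of the gene were averaged (-0.33, adjusted p = 0.194).

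Signalling lists gave single called genes and no shifted list. Of the YAP and TEAD targets (mean -0.08 ± 0.24, fry, adjusted p = 0.187) TEAD1 fell by 0.61, also 1 gene when adjusted over the list alone. Of the TGF-beta targets (mean -0.26 ± 0.39, fry, adjusted p = 0.357) the SMAD repressor SKIL fell by 0.97 (-0.40 and 0.02 on its other probe sets that were not dim) and TGFB1 by 0.45. TGFB1 passed in 8 of 21 alternatives, where its smallest fall was -0.20. ERK output genes had a mean of -0.06 ± 0.38 (fry, adjusted p = 0.954), in which cyclin D1 (CCND1) fell by 0.91 (-0.35 on its other probe set) and the receptor EPHA2 by 0.69. CCND1 and EPHA2 each passed in 7 of 19 alternatives, where their smallest falls were -0.35. Adjusted over the list alone these 2 fell and 1 rose, the phosphatase gene DUSP6 at 0.74 ± 0.66. Among immediate early genes (mean 0.08 ± 0.34, adjusted p = 0.754) FOS rose by 1.15 ± 0.75, and over the list alone 2 fell, JUND at -0.35 ± 0.29 and ATF3 at -0.72 ± 0.75. WNT targets had -0.05 ± 0.22 (0.933), NOTCH targets 0.15 ± 0.27 (0.417, with 2 that rose over the list alone) and p53 targets -0.18 ± 0.42 (0.583). NRF2 targets had -0.09 ± 0.29 (0.472) and NF-kB and inflammatory cytokines 0.16 ± 0.77 (0.883). The NF-kB mean was 0.01 without A549, which had 1.15, while H460 had -1.13. Interferon-stimulated genes had a mean of 0.25 ± 0.33 (fry, adjusted p = 0.295), and 0.15 without H358, which had 0.93. HERC5 stood at -0.38 ± 0.34, DDX60 at 0.62 ± 0.62 and PARP9 at 0.69 ± 0.82 (0.45 without H358), none of them called.

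The other metabolic and stress lists, and those of differentiation, stayed outside the calls. ATF4 targets had a mean of -0.39 ± 0.54 (fry, adjusted p = 0.187), with H661 at -1.41 and H23 at 0.18, PSAT1 at -0.76 ± 0.68 (-0.93 on its other probe set) and SLC3A2 at -0.48 ± 0.47. Of the endoplasmic reticulum chaperones (mean 0.18 ± 0.35, adjusted p = 0.419) EDEM1, which directs misfolded glycoproteins to degradation, rose by 0.59 ± 0.37 (2 rose over the list alone). Cholesterol synthesis had a mean of -0.09 ± 0.39 (adjusted p = 0.640) over the 16 of 23 list members that were tested, fatty acid synthesis -0.01 ± 0.25 (0.954), metallothioneins 0.19 ± 0.57 (0.564) and replication-dependent histones 0.09 ± 0.61 (0.799). In the lysosome and autophagy list (mean 0.05 ± 0.26, adjusted p = 0.954) the galactosidase gene GLA fell by 0.47 (SD 0.18), and over the list alone 1 rose and 1 fell. Lung epithelial differentiation genes had 0.36 ± 0.51 (0.187), and 0.23 without H358, which had 1.28. In that list MUC5B stood at 1.43 ± 2.06 (0.83 without A549, which had 5.57) and NKX2-1 at 0.62 ± 0.64 (-0.05 on its other probe set). Stemness markers had 0.03 ± 0.27 (0.681, but called at 0.18 with the filters at the 40th and 60th percentiles). Neuroendocrine markers had 0.35 ± 0.41 (0.357), where UCHL1 fell by 0.47 and CHGB stood at 0.94 ± 1.01 (2 rose and 1 fell over the list alone). UCHL1 passed in 3 of 19 alternatives, and CHGB in 0 of 21, with a lowest value of 0.46.

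Markers of cell types other than the cultured lines were measured as well. The leukocyte list shifted, with a mean of 0.18 ± 0.11 and higher values in 8 of 8 lines (fry, adjusted p = 0.0304; adjusted p = 0.562 with an estimated correlation), although 0 of its 8 tested members were called by limma over all genes or when adjusted over the list alone. Of these 8 genes 2 had an unadjusted p under 0.05, CD14 at 1.01 ± 1.33 (0.65 without A549, which had 3.52) and CD53 at 0.16 ± 0.12. The leukocyte call was lost on leaving out any one of H358, H1437, H23, H661 or H1703, and with the 18S level, lower by a mean of -1.15, as a covariate (mean 0.14, adjusted p = 0.252). Fibroblast and smooth muscle markers had a mean of 0.12 ± 0.20 (adjusted p = 0.472) and endothelial markers 0.07 ± 0.14 (0.472).

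Array controls were compared between the cultures as a check of RNA quality. The ratio of 3' to 5' probe sets, which rises when RNA is degraded, differed by -0.03 ± 0.07 for GAPDH (exact permutation p = 0.344) and by 0.09 ± 0.13 for ACTB (exact permutation p = 0.0859). Hybridisation spike-ins differed by 0.01 ± 0.19 (exact permutation p = 0.820) and poly-A spike-ins, added to the RNA before labelling, by 0.35 ± 0.50 (exact permutation p = 0.0938). Without H23 the poly-A spike-ins differed by 0.47 (exact permutation p = 0.0156) and the ACTB ratio by 0.11 (exact permutation p = 0.0469). With all lines the poly-A spike-ins were higher in 3D in 7 of 8. No date or batch of array processing was analysed, so a difference in handling between the cultures was not tested. Probe sets of 18S ribosomal RNA, which has no poly-A tail, were lower in 3D in 8 of 8 lines, by a mean of -1.15 ± 1.06. Their exact permutation p of 0.00781 is the smallest that 8 lines allow (0.0391 after Benjamini-Hochberg adjustment over the 5 controls). The 18S difference was -3.45 in H23, -0.13 in A427 and -0.08 in H1437, and without H23 the mean was -0.82. Of 5 relations over the 8 lines, 0 passed after adjustment. The mean of the 12 lowest genes had Pearson's r = 0.80 with 18S (permutation p = 0.0301, 0.150 adjusted), Spearman's rho = 0.67 (permutation p = 0.0831, 0.240 adjusted) and r = 0.78 without H23 and H1437. Pearson's r with 18S was -0.57 for the 12 highest (permutation p = 0.139; -0.72 without these 2 lines), 0.20 for hypoxia response (0.617; -0.85) and 0.19 for the replication and mitosis lists (0.672; 0.43). Between hypoxia response and the replication and mitosis lists it was -0.05 (0.909; -0.35 without H661 and H358).

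**Figure D3:**
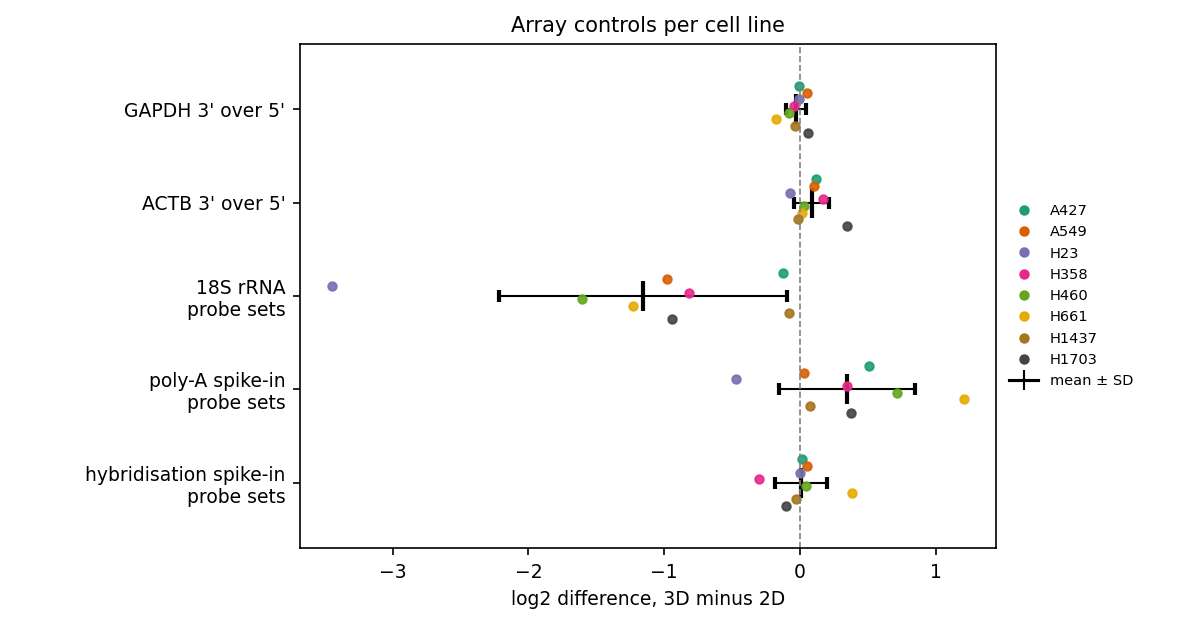
Log2 difference of 3D minus 2D (x axis) of 5 sets of array controls (y axis), 1 point per cell line and bars for the mean ± SD of 8 lines. The 18S rRNA probe sets lie below 0 in 8 of 8 lines, with H23 at -3.45, and the 3' over 5' ratios lie close to 0.

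The second comparison asked how the culture effect compares with the differences between lines. In 16 of 16 arrays the closest array was that of the same line in the other culture. Correlations of 2D with 3D ran from 0.780 in H23 to 0.924 in A427, and the highest between different lines was 0.330. The tested values are ratios to each probe set's own median, so expression shared by all lines is removed. Correlations between lines then lie near 0, and distances near 1, by construction, and do not measure how alike the lines are in level. Line accounted for a median of 86.8% of a gene's variance and culture for 2.10%, with 8.69% left as residual. The share of culture covers only the change common to the lines. With 1 array per line and culture, responses that differ between lines fall in the residual, together with noise. The mean distance between lines (1 minus r) was 1.03 in 2D and 1.02 in 3D. The difference of -0.00808 was not past an exact permutation test (p = 0.109, smallest possible 0.00781). With Spearman's correlation it was -0.00650 and passed (exact permutation p = 0.0234), as it did with Pearson's on leaving out A427, A549 or H1703, each time toward lines more alike in 3D. Without H358 it was 0.00139 and without H1437 0.00295, toward lines less alike, and neither passed. With the dim genes included it was 0.0137, so whether the lines were more alike in 3D depends on the setting.

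Lines differed in the size of their response, measured as the SD over genes of the 3D minus 2D difference. It was 0.359 in A427, with 135 genes at least 2-fold higher and 129 at least 2-fold lower. At the other end H661 had 0.608 (506 higher, 791 lower) and A549 0.591 (600 higher, 300 lower). The remaining lines were H358 at 0.585, H23 at 0.542, H460 at 0.501, H1437 at 0.491 and H1703 at 0.443. This order depends on the normalisation. After quantile normalisation H23 was highest at 0.646 and H661 stood at 0.523, while A427 stayed lowest at 0.383. Across genes, which are not independent replicates, each line's difference correlated with the mean of the other 7 at r = 0.199 in A427 and 0.245 in H1437, up to 0.485 in H358. These counts rest on 1 array per culture and have no replicate check.

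**Figure D4:**
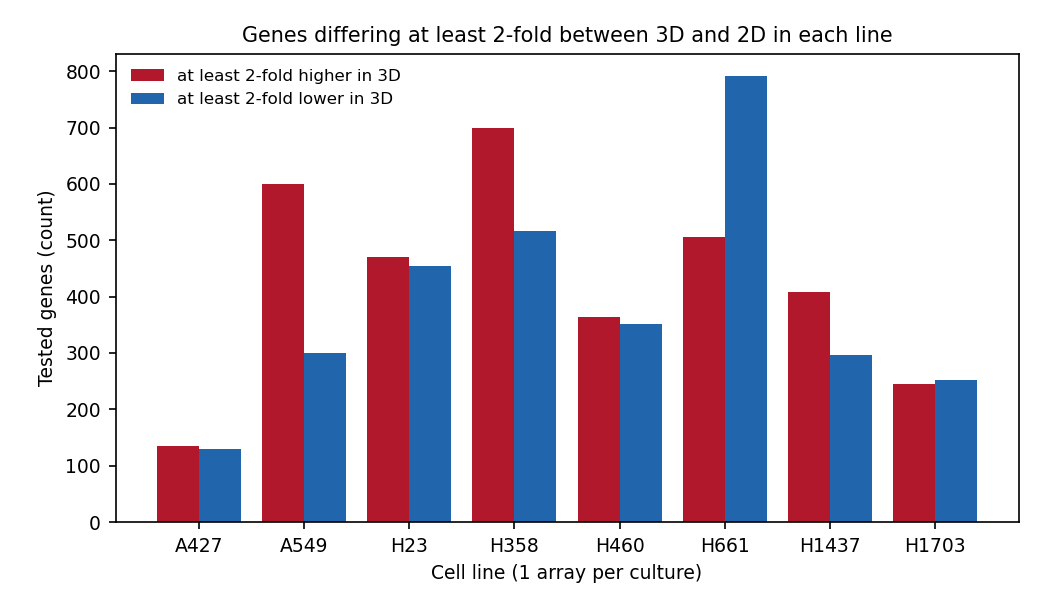
Number of tested genes (y axis) at least 2-fold higher (red) or lower (blue) in 3D than in 2D in each of 8 cell lines (x axis), from 1 array per culture. A427 has 135 higher and 129 lower, and H358 has 699 higher and 516 lower.

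Single lines had large changes of their own, given here as values without a test. Of the 48 such values 19 moved when all probe sets of a gene were averaged and 13 under quantile normalisation, and 0 changed sign. In A549 the mucosal scavenger receptor gene DMBT1 stood at 7.60, TSPAN8 at 6.97 and the adhesion molecule CEACAM6 at 7.22, against means of 0.09, 0.42 and 0.68 in the other 7 lines. CEACAM6 was also among the highest in H358 (4.97), next to the uncharacterised LOC105375172 (4.77), while the receptor kinase gene AXL had -3.03 there and TMEM158 -3.44. In H661 TXNIP, an inhibitor of thioredoxin and relative of ARRDC4, stood at 6.81 and the lipase gene LIPG at 4.73, with PRDM1 at -3.62 and TNFRSF9 at -3.82. H460 had the ceruloplasmin gene CP at 5.06 and the complement gene C1R at 3.97, and the chemokine genes CXCL3 and CXCL1 at -3.68 and -2.40. In H23 the glycolytic gene ALDOC had 4.19, against a mean of 0.90 in the other lines, and the plasminogen activator gene PLAU -2.98. H1437 had TFF3 at 3.41 and PTPRN2 at 3.81, and SPP1, which encodes osteopontin, at -4.62. In H1703 PDK3 stood at 3.52 and ALDOC at -1.34, the opposite sign to H23. A427 had S100A5 at 2.47 and IDUA at -1.15, smaller deviations than those leading in the other lines.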

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

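The tests on the largest falls were chosen after the result was seen, as were the fits with the 18S level as a covariate, the averages over probe sets that are not dim and the 40th percentile filter. The other tests were written before their results were seen. Of 72 sets of 8 line differences searched for a single line far from the rest, 2 held one, where chance alone would give 3.6. A549 stood apart in the basement membrane list, with a mean of 0.71 against 0.14 ± 0.13 in the other 7 lines. H23 stood apart in the 18S rRNA probe sets, at -3.45 against -0.82 ± 0.56. The 18S probe sets, which the planned comparisons of genes did not use, were lower in 3D by a mean of -1.15 ± 1.06. Whether the 854 called genes could arise from grouping by chance was tested by swapping 2D and 3D within lines. Of 100 assignments drawn from 128, 1 gave as many calls, the real one, and the highest of the others gave 1 gene. A random assignment within lines thus rarely gives such a count. Swaps cannot address a difference in handling shared by the 3D arrays, which would move with the labels. In 100 splits of the 16 arrays drawn from 6435 without regard to line, 1 gave as many, the real one, and the highest other gave 789. That split parted 6 lines in the same way as the real one, so it carries much of the same contrast.

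The first pattern weighed is the group of 12 genes with the largest falls, whose representative probe sets had a mean of -1.50 over lines. The choice of one probe set per gene cannot be told apart from a fall of the genes: the other probe sets, averaged within genes, had a median of -0.33 (22.1% of the representatives' -1.48), but genes picked by an extreme representative tend to have smaller others by that choice alone. Of those 21 others 8 were called, 7 in the same direction. A shift of ribosomal or other non-polyadenylated RNA between the cultures stays open and cannot be told apart from an effect of 3D culture itself: at no change of 18S the mean would be -0.96 (SE 0.22), but -0.73 (SE 0.28) without H23, too imprecise to decide. No measurement here separates the transcript parts that these probe sets read.

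The second pattern is the rise of hypoxia genes. For a shift of ribosomal or other non-polyadenylated RNA, the list mean at no 18S change would be 0.60 (SE 0.09), and 0.55 (SE 0.13) without H23. Beside a measured 0.57, that met the bound set in advance against it. The call nevertheless ended with 18S as a covariate (adjusted p = 0.0601); the mean did not shrink and its SE over lines was 0.056 before and 0.090 after, but why fry's p rose was not tested. Over 8 lines the list mean and 18S had r = 0.20 (permutation p = 0.617), but -0.85 without H23 and H1437, so the relation rests on few lines. H1437 and A427, with 18S differences of -0.08 and -0.13, had list means of 0.82 and 0.30. The list was thus higher in lines where 18S hardly changed, but how much of its mean the shift could account for cannot be told. For the choice of probe set, averaging all probe sets gave 0.50, which met the bound set in advance against it. That average includes the representatives, so the bound could hardly have failed. Averaging the probe sets that are not dim gave 0.62, so the others of that kind did not shrink the rise. For fewer dividing cells, the mean at no change of the replication and mitosis lists would be 0.56 (SE 0.13), which met the bound set in advance against it. Those lists only stand in for cell division and hardly followed the hypoxia mean over lines (r = -0.05), so that test is weak. Lower oxygen or altered metabolism in 3D may be proposed as a hypothesis, for which no oxygen measurement was analysed here.

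The third pattern is the fall of replication and mitosis genes, with a mean of -0.45 over both lists. For the choice of probe set, averaging all probe sets gave -0.48 (SE 0.10), which met the bound set in advance against it. That average includes the representatives, so the bound could hardly have failed. It lay as low as their own mean, so the other probe sets did not shrink the fall. For a shift of ribosomal or other non-polyadenylated RNA, the mean at no 18S change would be -0.40 (SE 0.15; 88.1% of the mean), which met the bound set in advance against it. That bound did not allow for 1 line deciding the fit: without H23, at -3.45 for 18S, the mean would be -0.27 (SE 0.20), within 2 SE of 0, so the shift cannot be told apart from a culture effect. Slower growth in 3D, a biological difference between the cultures, stays open and was not tested, because no growth rates were analysed here.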

How the results depend on the processing

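The fits with the 40th percentile filter, the mean of probe sets that are not dim and the 18S covariate were chosen after seeing the data. Pairing decided most calls: without the line as a block 1 gene was called (0 higher, 1 lower; 493 at an unadjusted p under 0.05) and 0 lists, since the differences between lines then enter the error. Without a filter 424 genes were called (151 higher, 273 lower), with the 60th percentile 268 (110, 158) and 3 lists, of which DNA replication and the proteasome were among the 7 and stemness was not (2 of the 7 had no test there), and with the 40th percentile 516 (199, 317) and 7 lists, 6 of them shared and stemness the other. Without probe sets of suffix s or x, 352 genes were lower. Testing each probe set gave 1843 genes, and a 1.5-fold minimum 369, by construction. Leaving out 1 line gave 155 to 923 genes, 56 to 329 higher, 88 to 594 lower, and 5 to 8 lists, with ribosome biogenesis and MYC targets added without A427. With 18S as a covariate limma called 0 genes (0 higher, 0 lower; 1359 at an unadjusted p under 0.05) and fry 0 lists, while the 854 genes kept their sign. Camera called 12 lists with a preset correlation, 6 of them shared with fry's 7 (the others were ATF4 targets, endoplasmic reticulum chaperones, interferon-stimulated genes, ribosomal proteins, ribosome biogenesis and lung epithelial differentiation), and 0 with an estimated one. Quantile normalisation, median centring, eBayes without trend, robust estimation and array weights gave 716 to 911 genes and 7 lists; averaging all probe sets gave 843 genes, of which 540 were shared with the 854. Over 23 alternatives the adjusted p ran from 1.82e-06 to 0.244 for hypoxia response (19 past the threshold), 6.60e-12 to 0.388 for DNA replication (20), 0.00328 to 0.458 for glycolysis (18), 4.20e-08 to 0.562 for the proteasome (20) and 1.38e-09 to 0.562 for mitosis (12), over 21 from 0.000142 to 0.244 for cytosolic heat shock (18), and over 22 from 0.00389 to 0.562 for leukocyte markers (13). The 77 called genes followed through the alternatives gave 1530 alternative values: 1038 stayed called in the same direction, 490 were no longer called, and 2 reversed, VHL (0.037) and NDUFA5 (0.28), both without probe sets of suffix s or x; for VHL the other probe set was then used. The spread between lines in 3D minus 2D was -0.00650 with Spearman's correlation (exact permutation p = 0.0234), 0.0137 without a filter, and -0.0200 to 0.00295 on leaving out 1 line, where it passed the exact permutation test without A427, A549 or H1703. After quantile normalisation the response size was 0.646 in H23 and 0.523 in H661. Leaving out 1 line gave 0.050 to 0.11 for the ACTB ratio, 0.23 to 0.47 for poly-A spike-ins and -0.045 to 0.054 for hybridisation spike-ins; the first 2 passed the exact permutation test without H23 (p = 0.0469 and 0.0156). Means of lists that were not called changed sign near 0. Without a filter these were matrix proteases (0.0357) and keratins (0.0175). With the 60th percentile they were interstitial matrix (-0.0032), matrix proteases (0.0093), mesenchymal state (0.0163), NRF2 targets (0.0080) and WNT targets (0.0223), and with the 40th interstitial matrix (-0.0032), matrix proteases (0.0093) and WNT targets (0.0345). With all probe sets averaged they were focal adhesion (-0.0183), keratins (0.0171), ERK output (0.0238) and stemness (-0.0347), and with those not dim -0.0091, 0.0534 for ERK output and -0.0157 for stemness. Cholesterol synthesis had 0.0917 without suffix s or x, and fatty acid synthesis 0.0085 with array weights. Quantile normalisation gave focal adhesion -0.0168, histones -0.0212 and stemness -0.0554. The 18S covariate gave YAP and TEAD targets 0.0181, matrix proteases 0.0448, keratins 0.229, ERK output 0.124 and endothelial markers -0.0279. Leaving out 1 line gave -0.0727 to 0.0369 for fatty acid synthesis, -0.0458 to 0.0617 for focal adhesion, -0.101 to 0.0862 for matrix proteases, -0.162 to 0.0044 for mesenchymal state, -0.150 to 0.0891 for keratins, -0.126 to 0.0122 for ERK output, -0.0074 to 0.0970 for lysosome, -0.0469 to 0.244 for histones and -0.0309 to 0.0732 for stemness. Except where stated, the cause was not tested.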

Other observations

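Genes outside the fixed lists, chosen here after their values were seen, added to the replication and mitosis genes that fell. The kinetochore gene CENPI fell by 1.06 (SD 0.25, adjusted p = 0.00597 from limma), lower in 8 of 8 lines. BRCA1 fell by 0.89 (SD 0.43), RAD51C by 0.87 (SD 0.45) and XRCC2 by 0.92 (SD 0.65), each in 8 of 8 lines. These 3 act in DNA repair, which was not tested as a group. XRCC2 passed in 10 of 18 alternatives, where its smallest fall was -0.54. FOXM1, a transcription factor of the late cell cycle, fell by 0.78 (SD 0.48), the phosphatase gene CDC25A by 0.80 (SD 0.63; -0.23 with 18S as a covariate) and TOP1, a DNA topoisomerase, by 0.99 (SD 0.75). Averaged over all its probe sets TOP1 stood at -0.63 and stayed called, and with 18S as a covariate it stood at -0.25 and was not called. No enrichment was tested for these genes.

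Among genes that rose, MIR210HG, the host gene of a hypoxia-induced microRNA, had 0.95 ± 0.70 and was higher in 8 of 8 lines. On their representative probe sets HLA-E, a non-classical antigen presentation molecule, rose by 0.81 ± 0.66 and TAPBPL, a relative of the peptide-loading protein tapasin, by 0.90 ± 0.61, both in 8 of 8 lines. Other probe sets gave 0.28 and 0.25 for HLA-E and 0.54 for TAPBPL, none of them called. IFITM2 and IFITM3, relatives of IFITM1, had 0.97 ± 0.85 and 0.77 ± 0.70, just outside the calls (limma, adjusted p = 0.0515 and 0.0768). All of these IFITM genes were read only by probe sets of suffix s or x, whose type allows matches to several transcripts. Their values may therefore not be independent. OGT, the enzyme that attaches N-acetylglucosamine to intracellular proteins, stood at 1.02 ± 0.73 and the sodium channel gene SCNN1A at 0.97 ± 0.79. Both calls rest on 1 probe set, since the other ones that were not dim lay between 0.08 and 0.38 for OGT and at -0.06 and -0.18 for SCNN1A, with 0 called. TXNIP, regulated by glucose as ARRDC4 is, was higher in 8 of 8 lines at 1.98 ± 2.07, not called on its representative probe set (adjusted p = 0.0783), with H661 at 6.81 and a mean of 1.29 without that line. Its other probe sets were called higher, at 1.89 (adjusted p = 0.0157 over all probe sets) and 2.00 (0.0498).

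Probe sets of one gene did not always move together. Tested one by one, 2261 of 27605 probe sets that were not dim were called, 817 higher and 1444 lower. They belonged to 1843 genes, of which 25 had probe sets called in both directions, DNAL1, ETNK1 and PSMC2 among them. The 5967 dim genes gave 0 calls when limma tested them alone (990 had an unadjusted p under 0.05) and 4 when they were tested together with all other genes.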
